A study of Homo sapiens with 3 samples.

How the data were processed

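RNA of 3 samples of transduced normal human bone marrow mononuclear cells, 1 per vector, was labelled and hybridised in 1 colour to Agilent arrays of design 026652. Per the labels, osteoclast growth factors were present for 48 h. Groups (EV, WT and P392L) come from the sample titles. Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, and probes are placed on the genome build hg18. The deposited scanner files give spot intensity on a linear scale. Per the file headers, the processed intensity had its background subtracted and was detrended within the array, low spots were set to a surrogate value, and no scaling between arrays was made. Flags per spot say whether it is well above background, saturated or an outlier, per the file headers.

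The authors' deposited value table gives a linear ratio per probe. Set against the scanner files it was the processed signal divided by 1 factor per array, close to the 75th percentile over probes, with a floor. Its log2 values correlated with the scanner signals at r of at least 0.9998 on each array over probes above the floor. The medians of its columns were 0.093 for EV, 0.076 for WT and 0.088 for P392L, so the values are scaled but not centred per gene, and with 1 colour there is no direction to settle. How its factors were set is not given in the sources used here. The table served as an alternative, and 0 deposited value columns were left unused.

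Each array held 44495 spots and 34127 probes, 999 of which had 10 spots. Control spots and spots marked as non-uniform or population outliers were left out. The log2 processed signal was averaged over the spots of a probe, a probe counted as well above background where most of its spots were, and the array's 75th percentile over probes was subtracted. A table of RefSeq genes for a GRCh38 assembly was used for names only. It named 24827 probes by accession, 1276 by symbol and 500 by an older symbol, and 7524 probes (22.0%) had no symbol. The 26603 named probes cover 20057 genes. Of several probes of a gene, the one with the highest mean among those well above background on at least 1 array was used, and 14909 genes had such a probe. Genes on chromosome Y, XIST, TSIX and genes known to vary with common germline variants (175 probes) were left out of every result.

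A gene was measured in a comparison if its probe was well above background on at least 1 of the arrays. Where it was so on 1 only, the fold is a bound ("at least N-fold") against the higher of the dim array's lowest signal among probes well above background and the probe's own signal there. That lowest signal was -3.79 log2 units relative to the 75th percentile on EV, -5.52 on WT and -5.62 on P392L, so bounds against EV are smaller. No gene was tested, since each group has 1 array. Genes at least 2-fold apart were counted for WT over EV, P392L over EV and P392L over WT, and genes set apart at least 2-fold from both other arrays were counted for each array. Each of 25 gene lists was summarised by the median log2 fold of its measured genes and by that median's percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these arrays and is no test of the vectors. Medians outside the middle 95% of random lists numbered 9 for WT over EV, 13 for P392L over EV and 15 for P392L over WT. For lists of unrelated genes 1.25 of 25 would lie there. Genes of a list can vary together, so that number is no measure of chance for these lists. TRAF6 stands in 2 lists, those of osteoclast genes and of autophagy. The lists, the comparisons and the alternatives other than those said to be added later were set before the data were examined.

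Genes were named by a rule. It takes SQSTM1, per comparison the 10 highest and 10 lowest folds and the 3 highest and 3 lowest bounds, up to 4 members per list with the largest folds, and per array the 5 genes set furthest apart each way. These highest and lowest folds and bounds belong to genes with an official symbol, a signal above the median of probes well above background on the brighter array, and no probe that goes the other way. Where fewer are named, the others are in the counts. Probes of related genes and copies (the globin genes HBG1 and HBBP1, CCL4L1 and CCL4, and pseudogenes such as DEFA8P, CXCR2P1 and BMS1P20) can share signal with their relatives, so these names are uncertain.

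Alternatives were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile normalization, the median of probes well above background on all arrays as the scale, the authors' table, a filter for genes well above background on both arrays, no filter, the mean over a gene's probes, and outlier spots kept. Corrections added after seeing the data were a lowess over signal level and the same followed by a lowess over the GC content of the probe (span 0.3, statsmodels 0.14.6). Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Folds and lists were tested on simulated data. For P392L over WT, with 14050 genes and noise of SD 0.1, 100 of 100 genes changed by 1.5 log2 units and 100 of 100 changed by 3 were recovered, 0 other genes passed 2-fold, and 3 of 100 unchanged lists lay outside the middle 95%. For WT over EV and P392L over EV the recovery was the same, and 6 and 7 of 100 unchanged lists lay outside it. This checks the code and not the accuracy of the folds, since the simulated noise lies far below the SD between probes of a gene. Precision is limited by the number of arrays. The SDs over spots and over probes cover technical spread within these arrays.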

Results

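Gene expression was measured on 3 one-colour Agilent arrays of RNA from normal human bone marrow mononuclear cells. The cells had been transduced with a retroviral vector and then kept with M-CSF and RANKL, the growth factors that drive osteoclast formation, for 48 h. The empty vector (EV), a vector with wild-type p62 (WT) and a vector with p62 P392L (P392L) had 1 array each. p62, encoded by SQSTM1, is a scaffold of RANK and NF-κB signalling and a receptor for ubiquitinated cargo in autophagy, and P392L lies in its ubiquitin-associated domain and recurs in Paget's disease of bone. With no replicates, none of the differences below has a check against the spread between cultures, and no p-value is given. The 75th percentile of the probe signals was 255 on the EV array, 824 on the WT array and 969 on the P392L array. Probes well above background made up 51.6%, 61.3% and 61.8% of 34127 on these arrays. Replicate spots of a probe had a median SD of 0.07 log2 units on the EV array, 0.07 on the WT array and 0.05 on the P392L array. Log2 folds from different probes of a gene had an SD per probe of 0.71 for WT over EV, 0.83 for P392L over EV and 0.76 for P392L over WT. EV and WT lay on slide 1 and scan day 1, and P392L lay alone on slide 2 and scan day 2, so in comparisons with P392L the slide and the vector cannot be told apart.

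The single SQSTM1 probe gave a scaled log2 signal of 3.50 on the EV array, 2.98 on the WT array and 4.20 on the P392L array. It was 1.44-fold lower on WT than on EV, 1.62-fold higher on P392L than on EV and 2.32-fold higher on P392L than on WT. The probe lies on chromosome 5 at 179196315 to 179196374 of hg18, plus strand, and has a stop codon in each of its 3 reading frames, so it lies outside the coding sequence. It therefore does not check the vector's transcript unless the vector holds that part of the gene.

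The comparison of P392L with WT asks what the mutation changes in transduced marrow cells under osteoclast growth factors. Genes of granulocyte precursors and of dividing cells were far lower on the P392L array, and T cell, NF-κB, chemokine and cytokine genes were higher. Of 14707 genes measured, 2661 were at least 2-fold higher on P392L and 3291 at least 2-fold lower, of which 330 and 544 were bounds, since the gene was well above background on 1 of the arrays only. Neutrophil granule genes led the lowest folds. PRTN3, the gene of proteinase 3, was 2935-fold lower, MPO, which encodes myeloperoxidase, 614-fold lower, AZU1 586-fold lower and ELANE, neutrophil elastase, 516-fold lower. OLFM4 was 1662-fold lower, TFF3 791-fold lower, CEACAM8 397-fold lower, CTSG 346-fold lower and LTF 325-fold lower. CEACAM6 was at least 598-fold lower, PCOLCE2 at least 410.4-fold lower and ABCA13 at least 284-fold lower.

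Of the granulocyte and precursor list, 16 of 20 measured genes were at least 2-fold lower on P392L than on WT, with a median log2 fold of -7.53, below each of 10000 random lists matched on expression. CXCR2, a receptor of mature neutrophils that was named after its values were seen, was 2.83-fold higher. Of the cell cycle list 26 of 26 genes were at least 2-fold lower (median -4.78, and up to -3.66 in the alternatives). MKI67, the gene of the proliferation antigen Ki-67, was at least 104-fold lower, CENPF 88.4-fold lower and BIRC5, which encodes survivin, 66.7-fold lower. The size of the MKI67 value may depend on the probe, since its fold of WT over EV reversed with the mean over its probes. Eosinophil granule genes were lower too, PRG2 by 235-fold, EPX by at least 90.5-fold and RNASE3 by 73.8-fold. Their mast cell, basophil and eosinophil list had 12 of 15 genes lower and 2 higher (median -2.77). Of the erythroid list 14 of 17 genes were lower (median -2.16). Among these RHAG, which encodes a red cell membrane channel, was at least 117-fold lower.

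**Figure D1:**
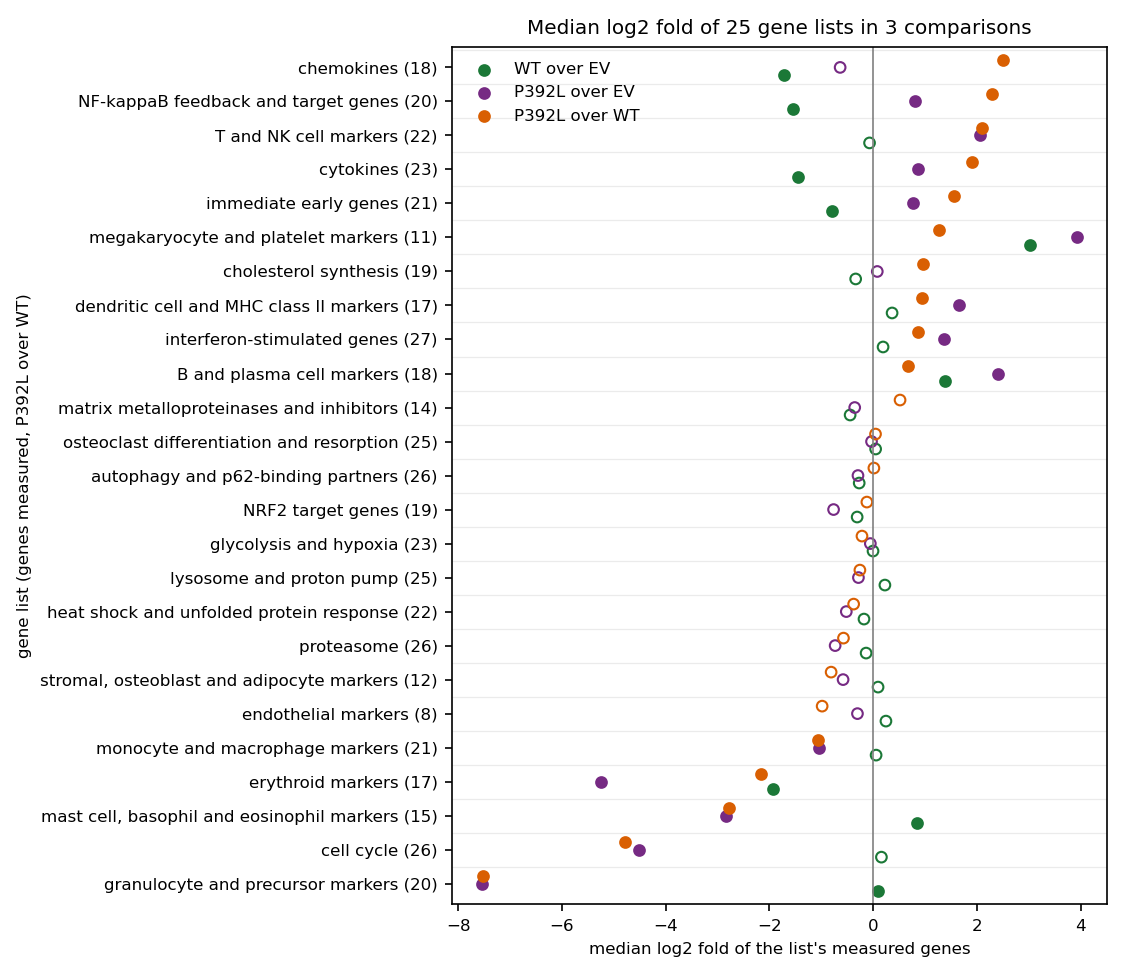
Median log2 fold (x axis) of the measured genes of 25 lists (y axis) for WT over EV, P392L over EV and P392L over WT, with the number of genes measured in the last comparison in brackets. Filled points lie outside the middle 95% of 10000 random lists matched on expression and open points inside it. Granulocyte and cell cycle lists lie near -7.53 and -4.78 for P392L over WT and near 0 for WT over EV.

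T and NK cell genes were higher on P392L than on WT in 21 of 22 cases, with a median log2 fold of 2.09. CD28, the costimulatory receptor, was 11.5-fold higher, CD5 9.74-fold higher, KLRB1 7.42-fold higher and CD3E, a chain of the T cell receptor complex, 6.95-fold higher. NKG7, named after its values were seen, was 2.02-fold lower. The megakaryocyte and platelet list had 6 of 11 genes higher and 0 lower (median 1.26), among them TUBB1 at 11.6-fold higher and NRGN at 5.86-fold higher. In the dendritic cell and MHC class II list 7 of 17 genes were higher and 2 lower (median 0.94). CCR7 and CD83 were 15.0-fold higher and 7.28-fold higher. The 2 lower genes were FLT3 (13.9-fold lower) and CLEC4C (at least 7.09-fold lower). Which cells these signals came from was not tested. The B and plasma cell list had a median of 0.67, with 7 of 18 genes higher and 3 lower. The 3 lower genes, all of lymphocyte precursors, were VPREB1 (at least 214-fold lower), RAG1 (35.6-fold lower) and DNTT (at least 6.88-fold lower). Other genes of B cell precursors, chosen here after their values were seen, lay within 2-fold, among them IGLL1 (1.33-fold higher) and VPREB3 (1.43-fold lower). The IGLL1 value depends on the probe, since its fold of P392L over EV reversed with the mean over its probes. These folds do not show whether B cell precursors were kept. BLK, a kinase of mature B cells, was 10.3-fold higher.

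Monocyte and macrophage genes divided. Of 21 measured, 11 were at least 2-fold lower on P392L than on WT and 3 higher (median -1.06, percentile 0.1 among random lists). In an alternative the list came back inside the middle 95% (percentile up to 3.67). APOC1 was at least 92.7-fold lower, CHIT1, a chitinase of lipid-laden macrophages, 76.1-fold lower, APOE 13.6-fold lower and C1QC, a chain of complement C1q, 10.6-fold lower. The higher genes, named after their values were seen, were CD14 at 2.58-fold higher, CD163 at 2.11-fold higher and MARCO at 2.97-fold higher. The stromal, osteoblast and adipocyte list (median -0.81, percentile 4.84) and the endothelial list (median -0.98, percentile 4.89, 8 genes) lay within the middle 95% of random lists, although the stromal list left it in an alternative (percentile down to 1.32). Within them CXCL12, a chemokine of marrow stroma, was at least 143-fold lower, ERG at least 18.4-fold lower and ALPL, alkaline phosphatase of osteoblasts and neutrophils, 38.5-fold higher.

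NF-κB feedback and target genes were higher on P392L than on WT in 18 of 20 cases and lower in 0, with a median log2 fold of 2.28, above each random list. RELB, a subunit of the non-canonical NF-κB dimer, was 18.5-fold higher, its partner NFKB2 10.4-fold higher, the adhesion receptor ICAM1 13.9-fold higher and BIRC3, which encodes cIAP2, 9.59-fold higher. Of 18 chemokines 11 were higher and 2 lower (median 2.51). CCL7 was at least 23.9-fold higher, and the neutrophil attractant CXCL5 and the monocyte attractant CCL2 were each 15.2-fold higher. CCL18, a product of alternatively activated macrophages, was at least 14.1-fold lower. Of 23 cytokines 16 were higher and 2 lower (median 1.90), with IL1A 47.1-fold higher, LTA 19.8-fold higher, IL10 14.2-fold higher and IL6 11.9-fold higher. Immediate early genes were higher in 16 of 21 cases and lower in 2 (median 1.56), the latter FOSB at 3.24-fold lower and FOSL1 at 2.02-fold lower, both chosen in this comparison after their values were seen. EGR3 was 18.7-fold higher, NR4A3 16.8-fold higher and DUSP2 8.54-fold higher. Of the interferon-stimulated genes 11 of 27 were higher and 1 lower (median 0.87), led by IFIT2 at 35.5-fold higher, IFIT3 at 18.2-fold higher and OASL at 17.7-fold higher. T and NK cell markers were higher and granulocyte precursor markers lower in the same comparison, with medians of 2.09 and -7.53.

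**Figure D2:**
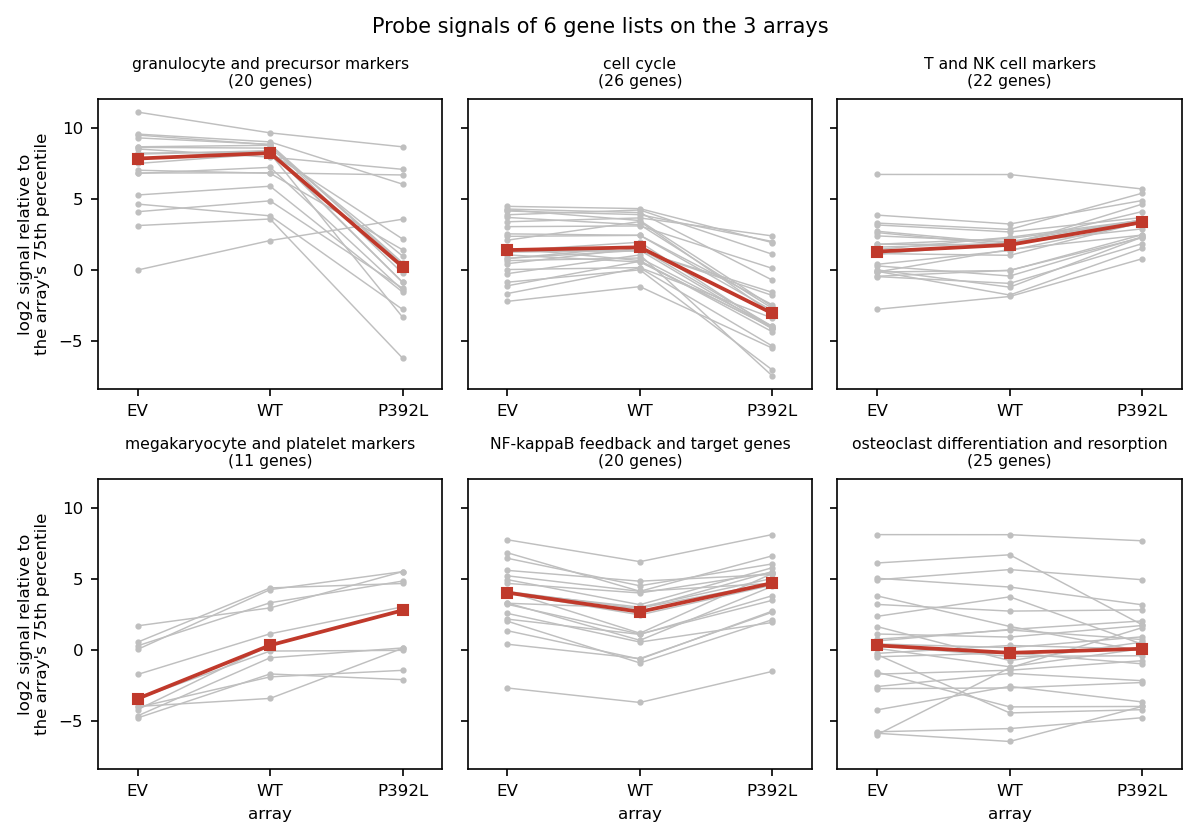
Scaled log2 signal (y axis, relative to the array's 75th percentile) of the genes of 6 lists on the EV, WT and P392L arrays (x axis). Grey lines are single genes and red squares list medians. The granulocyte median was 7.86 on EV, 8.25 on WT and 0.25 on P392L, and the NF-κB median 4.04, 2.69 and 4.72.

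The osteoclast differentiation and resorption list had no shared direction between P392L and WT. Its median log2 fold was 0.05, at percentile 71.1 of random lists, with 4 of 25 genes at least 2-fold higher, 5 lower and 16 in between. MMP9, a gelatinase that neutrophil precursors also make, was 30.4-fold lower, OSCAR, an osteoclast-associated receptor, 10.1-fold lower, and CA2, a carbonic anhydrase also found in erythroid cells, 3.34-fold lower. ITGB3, the integrin β3 chain of osteoclasts and platelets, was 7.08-fold higher. Apart from NF-κB genes, the lists tied to p62 function lay within the middle 95% of random lists. The median was 0.02 for autophagy and p62-binding partners, -0.12 for NRF2 targets, -0.57 for the proteasome, -0.38 for heat shock and the unfolded protein response and -0.25 for lysosome and proton pump. Glycolysis and hypoxia genes (-0.21) and matrix metalloproteinases and inhibitors (0.52) also did, the latter not in every alternative (percentile up to 98.1). Within these lists ATG7, an autophagy enzyme, was 6.83-fold lower, the deubiquitinase CYLD 3.03-fold higher, AKR1C1 12.2-fold lower, TXNRD1, thioredoxin reductase, 4.34-fold higher and ADM, the gene of adrenomedullin, 14.3-fold higher. Cholesterol synthesis lay above the middle 95%, with 9 of 19 genes higher and 3 lower (median 0.96), STARD4 at 4.86-fold higher and DHCR7 at 3.75-fold lower.

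Among the highest folds outside these lists were C4BPA, a complement regulator, at 74.9-fold higher, CXCR5 at 47.9-fold higher, IGFBP3 at 44.1-fold higher, IL2RA, the inducible chain of the interleukin 2 receptor, at 36.7-fold higher, the cell cycle inhibitor CDKN1A at 32.8-fold higher and the T cell costimulatory ligand CD70 at 31.7-fold higher. MSC was at least 66.4-fold higher and GPR15 at least 65.9-fold higher. A second probe, where a gene had one, showed the direction of the first for 927 of 1134 genes past 2-fold (81.7%). Quantities in this comparison describe 1 pair of arrays from different slides.

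Set against the empty vector, P392L had 2450 genes at least 2-fold higher and 3308 lower of 13237 measured. Higher genes made up 42.5% of these, and 31.4% with the normexp background correction. Without the filter on dim probes 8138 genes were lower. Platelet and lymphoid genes led the higher side and granulocyte, erythroid and cell cycle genes the lower. MYL9, the myosin light chain of platelets and smooth muscle, was 103-fold higher, GNG11 78.4-fold higher, RGS18 60.9-fold higher, the platelet chemokine PPBP 44.3-fold higher and JCHAIN, the joining chain of secreted antibodies, 38.2-fold higher. TREML1 was at least 95.9-fold higher, MLH3 at least 62.6-fold higher and ITGB3 at least 41.2-fold higher. A total of 11 of 11 measured megakaryocyte and platelet genes were at least 2-fold higher (median 3.94), as were 19 of 22 T and NK cell genes (1 lower, median 2.05), 14 of 17 B and plasma cell genes (2 lower, median 2.41) and 11 of 13 dendritic cell and MHC class II genes (1 lower, median 1.66). The lower B cell genes were VPREB1 at at least 33.7-fold lower and RAG1, named after its values were seen, at 4.38-fold lower. CIITA, the regulator of MHC class II, was 5.77-fold higher and KLRD1, an NK cell receptor, 11.8-fold higher.

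On the lower side, PRTN3 was 1809-fold lower on P392L than on EV, CTSG 556-fold lower and the globin gene HBG1 355-fold lower, while RHAG was at least 449-fold lower. Lower genes made up 18 of 20 of the granulocyte list (1 higher, median -7.54), 17 of 17 of the erythroid list (median -5.26), 25 of 26 of the cell cycle list (median -4.52) and 8 of 13 of the mast cell, basophil and eosinophil list (2 higher, median -2.84). Over the alternatives the cell cycle median ran up to -3.02 and the mast cell median up to -1.41. Monocyte and macrophage genes had 10 of 20 lower and 4 higher (median -1.04). The median of NF-κB genes was 0.80, with 8 of 20 at least 2-fold higher and 0 lower, and BIRC3 and TNFAIP3, the gene of A20, were 4.77-fold higher and 3.14-fold higher. Interferon-stimulated genes had 18 of 26 higher and 3 lower (median 1.37). IFI44L was 10.5-fold higher and HERC5 9.63-fold higher, while the largest changes were those of IFI27 at at least 18.0-fold lower and CXCL9 at 14.3-fold lower. Cytokines had 9 of 21 genes higher and 4 lower (median 0.87), with IL1A 11.1-fold higher but CSF3 7.94-fold lower and INHBA, the gene of an activin subunit, 5.91-fold lower. Immediate early genes had 8 of 21 higher and 2 lower (median 0.76). JUNB was 4.22-fold higher, and the largest folds of that list were those of FOSL1 at 8.38-fold lower and FOSB at 5.11-fold lower. Chemokines divided, with 5 of 19 higher and 9 lower (median -0.64, percentile 15.3): CXCL5 was 7.68-fold higher and CCL19 47.5-fold lower.

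The osteoclast list had a median of -0.03 for P392L over EV, at percentile 53.7, with 2 of 23 genes higher and 7 lower. MMP9 was 20.4-fold lower, CA2 14.8-fold lower and OCSTAMP, a fusion gene of osteoclasts, 14.6-fold lower. OCSTAMP was also 17.1-fold lower on WT than on EV, so EV stands apart from both other arrays in it. The remaining lists lay within the middle 95% of random lists. Their medians were -0.73 for the proteasome, -0.76 for NRF2 targets, -0.52 for heat shock, -0.29 for autophagy, -0.28 for lysosome, -0.05 for glycolysis, 0.08 for cholesterol synthesis, -0.35 for metalloproteinases, -0.58 for stromal and -0.30 for endothelial genes. Of these calls 3 depend on the processing: in an alternative NRF2 targets (percentile down to 1.49), stromal genes (down to 2.10) and endothelial genes (up to 100, with a median of up to 2.90) left the middle 95%. TRIB3, a stress-induced pseudokinase, was 26.3-fold lower and GCLC, which limits glutathione synthesis, 8.60-fold lower.

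The comparison of WT with EV, which share slide 1 and scan day 1, asks what the wild-type p62 vector does in these cells. No value here shows more p62 on WT, where the SQSTM1 probe was lower. NF-κB, chemokine, cytokine and immediate early genes were lower on WT, and platelet and B cell genes higher. Of 13104 genes measured 1792 were at least 2-fold higher and 2245 lower. Higher genes made up 44.4% of these, and 29.7% with the normexp background correction. Without the filter on dim probes 6528 genes were lower. NF-κB genes were lower in 17 of 20 cases and higher in 0, with a median log2 fold of -1.55, below each random list. RELB was 7.73-fold lower, IL4I1 7.64-fold lower, SOD2, mitochondrial superoxide dismutase, 6.55-fold lower and ICAM1 6.17-fold lower. Chemokines were lower in 13 of 18 cases (median -1.71), CCL7 by at least 103-fold, CCL19 by 48.4-fold and CCL2 by 32.8-fold. Cytokines were lower in 11 of 20 cases and higher in 2 (median -1.45), with CSF3, the gene of G-CSF, 31.9-fold lower and IL10 11.9-fold lower. Immediate early genes had 8 of 21 lower and 0 higher (median -0.79), among them EGR3 at 11.3-fold lower. Monocyte and macrophage markers (median 0.06) and T and NK cell markers (-0.07) lay within the middle 95% of random lists in this comparison.

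**Figure D3:**
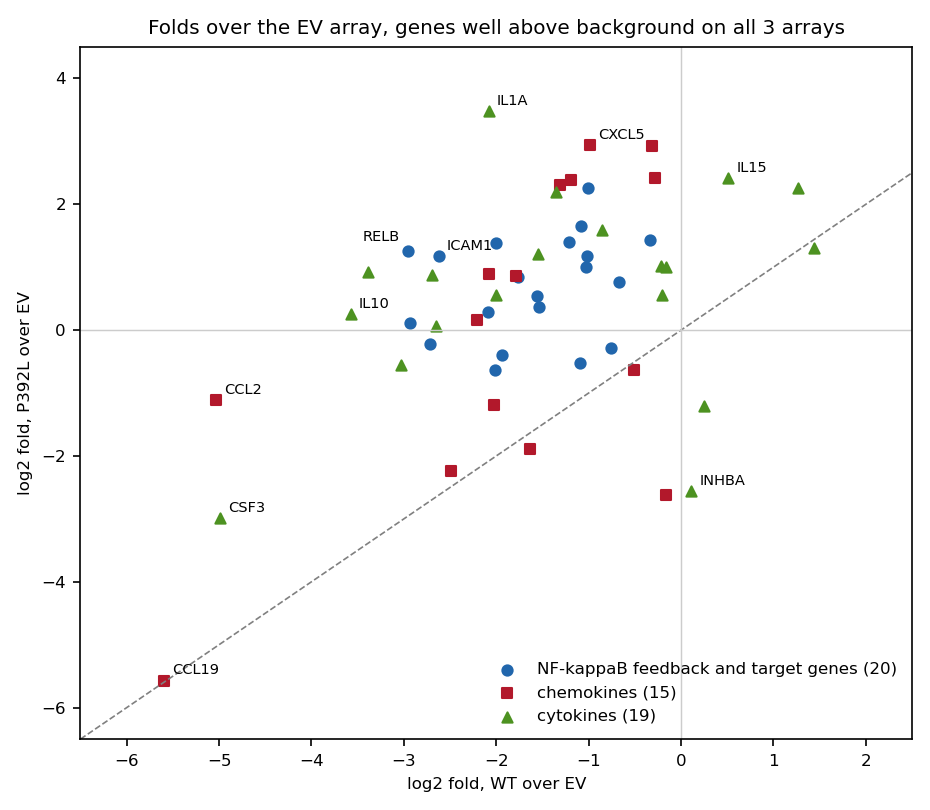
Log2 fold of WT over EV (x axis) against P392L over EV (y axis) for 54 genes of 3 lists that were well above background on all 3 arrays. Points above the dashed line, 48 of the 54, were higher on P392L than on WT. Both axes share the EV array, so their correlation has no meaning of its own.

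Interferon-stimulated genes went both ways between WT and EV, with 9 of 26 higher and 8 lower (median 0.19). IFI44L was 10.4-fold higher and CXCL9 24.9-fold lower. Platelet genes were higher on WT in 10 of 11 cases (median 3.03, and 2.01 or more in the alternatives), with PPBP 18.5-fold higher, PF4, platelet factor 4, 14.1-fold higher and TREML1 at least 17.4-fold higher. B and plasma cell genes were higher in 10 of 18 cases and lower in 1 (median 1.38), with MZB1 9.40-fold higher and JCHAIN 8.30-fold higher. The mast cell, basophil and eosinophil list had 5 of 14 genes higher (median 0.84), with MS4A2, a chain of the IgE receptor, at least 9.96-fold higher. Erythroid genes were lower in 15 of 17 cases (median -1.93), HBG1 by 142-fold, ALAS2, the first enzyme of heme synthesis in red cells, by 9.44-fold and SLC4A1 by 8.66-fold. The granulocyte list lay above the middle 95% of random lists (median 0.10, percentile 99.5), with 18 of 20 genes within 2-fold. Dendritic cell and MHC class II (0.37), stromal (0.10), endothelial (0.25) and cell cycle (0.16) lists lay within the middle 95%, the first of them not in every alternative (percentile up to 99.1).

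The osteoclast list had a median of 0.05 for WT over EV, at percentile 48.0, with 3 of 23 genes higher and 5 lower. OCSTAMP was 17.1-fold lower, CALCR, the calcitonin receptor, 5.43-fold lower and ACP5, the gene of tartrate-resistant acid phosphatase, 5.25-fold lower, while ITGB3 was at least 5.81-fold higher. OCSTAMP and CALCR differed by 1.17-fold and 1.02-fold between P392L and WT, so their difference between WT and EV is not one of WT alone. OCSTAMP, CALCR and ACP5 are among 4 genes of the list set apart higher on EV. Whether unspecific signal on the EV array contributes to them was not tested. ACP5 was 2.47-fold higher on P392L than on WT. Autophagy and p62-binding partners had a median of -0.27, at percentile 2.82, just inside the middle 95% and outside it in an alternative (percentile down to 1.01). Within that list OPTN, like p62 an autophagy receptor, was 6.70-fold lower, MAP1LC3B 4.26-fold lower and ATG7 2.84-fold higher. Medians of the other lists lay within the middle 95%: -0.31 for NRF2 targets, -0.13 for the proteasome, -0.18 for heat shock, 0.23 for lysosome, -0.00 for glycolysis, -0.34 for cholesterol synthesis and -0.44 for metalloproteinases. Cholesterol synthesis left it in an alternative (percentile down to 1.14). CHAC1, a glutathione-degrading stress gene, was 18.0-fold lower. The lowest folds of all held genes that marrow cells are not known to use, such as the hair keratin KRT85 at 53.8-fold lower. Of 106 measured olfactory receptor, taste receptor, keratin-associated and β-defensin genes, 43 were at least 2-fold higher on EV than on both other arrays, and 0 were so on WT or on P392L. The 0 counts are limited by the lowest signal well above background, -3.79 on EV against -5.52 on WT and -5.62 on P392L. Genes near or below the EV value on WT or P392L could not be called 2-fold above EV.

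Each array was also set against both others. On P392L 1464 genes were at least 2-fold higher and 1822 lower than on each of the others, on EV 1469 and 671, and on WT 793 and 684. These counts depend on the processing, which limits comparing the arrays by them: on EV 5040 genes were higher without the filter on dim probes and 214 lower with normexp, and on WT 473 were higher with normexp. The genes furthest apart on P392L were C4BPA, PIK3IP1, TMEM140, CCL4L1 and ALPL on the higher side, 31.4-fold to 21.4-fold from the nearer array with bounds included, and PRTN3, AZU1, MPO, ELANE and TFF3 on the lower (1809-fold to 461-fold). WT stood apart through PPFIA4, FGF13, RNU2-2, MOSPD2 and ZNF280D, 27.9-fold to 10.2-fold higher than the nearer array with bounds included, and through CCL7, MSC, EDN1, GPR15 and DUSP4, 23.9-fold to 16.8-fold lower. EV stood apart through HBBP1, HBG1, NFASC, HCRT and GSTA3 on the higher side and PPBP, TREML1, BMS1P20, RGS18 and PF4 on the lower. Of the lists, 16 of the NF-κB genes were at least 2-fold lower on WT than on both other arrays, 8 were higher on P392L than on both and 0 were set apart on EV. Of the chemokines 7 were set apart lower on WT but 8 higher on EV, so their difference between WT and EV is not one of WT alone. CCL19, for example, differed by 1.02-fold between P392L and WT. For the T and NK cell list 19 genes were set apart higher on P392L, and for the platelet list 10 genes were set apart lower on EV. Across probes, log2 signals correlated with r = 0.937 between WT and EV, 0.929 between P392L and WT and 0.896 between P392L and EV. These correlations run over probes, which are not independent replicates.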

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

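The tests of scaling, slide, cell loss, distance from background, probe GC content, unspecific signal and cell content in this part were chosen only after the results were seen, and the distance from background replaced a share that decided nothing. Signal outside the main measurement came from probes with no gene symbol. Of these, 231 were at least 2-fold higher on WT than on EV and 565 at least 2-fold higher on P392L than on EV, among 2373 and 2608 measured. Lower than on EV were 1019 (42.9%) on WT and 913 (35.0%) on P392L.

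Granulocyte precursor and cell cycle genes were far lower on P392L than on WT, with list medians of -7.53 and -4.78. Scaling and background correction are argued against, since the highest median over the 10 alternatives was -7.11 for the granulocyte list and -3.66 for the cell cycle list. A loss of marrow precursors with all other cells in unchanged proportions was not settled. The T and NK cell median exceeded the monocyte and macrophage median by 3.15 (bootstrap SE over genes 0.646). That explanation needs both to move alike only if the lost precursors express none of the monocyte and macrophage list, which was not tested. The slide and scan day stay open, because 0 arrays of another group lie on the P392L slide, and so do a difference in cell content between cultures before or during the 48 h and an effect of P392L itself, neither of which these data test.

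On EV 1469 genes were at least 2-fold higher than on both other arrays, although EV was the dimmest array. Signal near background was not settled as a cause. These genes lay a median of 3.72 log2 units above the lowest signal of a probe well above background on EV (lower quartile 1.56). Most were therefore clear of that signal, but each had to be well above background on EV to be counted. No other set of genes was compared with them for this distance. A trend with probe GC content is argued against, since 92.4% of the genes (1358) stayed at least 2-fold higher after a correction for signal level and GC. Unspecific or non-messenger signal on EV may account for part: 40.6% of 106 olfactory receptor, taste receptor, keratin-associated and β-defensin genes were among these genes, against at most 28.3% in 10000 random sets matched on expression. Whether the erythroid genes on EV (15 of the list set apart higher) or the osteoclast genes (4 of theirs) share that source was not tested. Neither was an effect of the vector.

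NF-κB genes were lower on WT than on EV, with a list median of -1.55. The lower signal of EV and a trend with probe GC are argued against, since the median after that correction was -1.30. Fewer monocytes, granulocytes or T cells on WT are argued against by their list medians, the lowest of which was -0.069. The slide and scan day are argued against too, since both lie on 1 slide. Other cell lists did move, with medians of 3.03 for platelet, 1.38 for B and plasma cell and -1.93 for erythroid genes. A difference in those or other cells, in the RNA or labelling of each array, or between the cultures in handling or timing stays open. So does an effect of wild-type p62, and with 1 array each none of these was tested.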

How the results depend on the processing

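The tests with lowess corrections over signal level and over probe GC content were added only after the data were seen. Over 10 alternatives, 169 of 180 main counts and SQSTM1 folds stayed the same, 11 moved and 0 reversed. A count was called the same within a fixed ratio of its main value, and no count could be called reversed. A SQSTM1 fold was called the same within the SD per probe (0.71 to 0.83). It could be called reversed only if past 2-fold in the main setting. Both filter choices and the mean over its single probe leave the SQSTM1 fold unchanged by construction. Genes at least 2-fold higher numbered 917 for WT over EV with normexp (main 1792) and 1459 for P392L over EV (main 2450). With normexp, 214 genes were set apart lower on EV (main 671), 473 higher on WT (main 793) and 965 higher on P392L (main 1464). The offset of 50 in normexp shrinks folds of dim genes by construction. With no filter, 6528 genes were lower on WT than on EV (main 2245) and 8138 lower on P392L than on EV (main 3308). Set apart were then 5040 genes higher on EV (main 1469), 1013 lower on EV, 1336 lower on WT (main 684) and 3140 lower on P392L (main 1822). Without the filter, probes below background enter, and these sit nearer to the scaling point on the dim EV array, so signal over background limits what the counts against EV can show. Higher genes then made up 26.8% for WT over EV and 27.2% for P392L over EV. SQSTM1 ranged from -0.52 to -0.27 for WT over EV, from 0.69 to 1.09 for P392L over EV and from 1.19 to 1.39 for P392L over WT. For P392L over EV it passed 2-fold with quantile normalization (1.08) and with both lowess corrections (up to 1.09).

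Of 750 list medians 641 stayed the same, 109 moved and 0 reversed. A median was called the same within a standard error taken from the SD per probe. Only lists outside the middle 95% in the main setting could be called reversed. Medians outside the middle 95% of random lists numbered 9 to 12 for WT over EV, 13 to 14 for P392L over EV and 15 to 16 for P392L over WT. The monocyte and macrophage list for P392L over WT came back inside it in an alternative (percentile up to 3.67), while lists inside it in the main setting went outside in at least 1 alternative. For WT over EV these were autophagy (percentile down to 1.01), cholesterol synthesis (down to 1.14) and dendritic cell and MHC class II genes (up to 99.1). For P392L over EV they were NRF2 targets (down to 1.49), stromal genes (down to 2.10) and endothelial genes (up to 100), and for P392L over WT stromal genes (down to 1.32) and metalloproteinases (up to 98.1). The endothelial median for P392L over EV ran from -1.76 to 2.90, so it has no direction. The stromal median for P392L over EV ran from -1.74 to 0.08. Other medians that came more than 1 log2 unit nearer to 0 in an alternative were those of the cell cycle (up to -3.02 for P392L over EV and -3.66 for P392L over WT), the mast cell list (-1.41) and the granulocyte list (-6.46) for P392L over EV, and the platelet list for WT over EV (2.01). Folds of named genes were called the same within the SD per probe, and only those past 2-fold could be called reversed. Of 4543 folds of named genes 4336 stayed the same, 204 moved and 3 reversed, the last given next. MKI67 for WT over EV was 1.32 in the main setting and -1.31 with the mean over its probes, and XCL1 for WT over EV was 1.19 and -0.017 with normexp. IGLL1 for P392L over EV was 3.45 and -0.62 with the mean over its probes. For these the cause was not tested. Quantile normalization put the median of all genes at 0.17 for WT over EV (main 0.06) and 0.02 for P392L over EV (main -0.09). No paired analysis was possible because each group has 1 array.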

Other observations

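The gene lists in this part were drawn up after the main folds were seen, with the genes that prompted them left out, and their tests were fixed before the lists' values were seen. Genes named here were chosen after their values were seen. T cell activation genes were higher on P392L than on WT in 14 of 16 cases, with a median log2 fold of 2.06. IFNG, the gene of interferon γ, was 16.8-fold higher, TNFRSF18 12.2-fold higher, ICOS 11.1-fold higher and XCL1 10.2-fold higher, and CD38 was 3.14-fold lower. On WT they were lower than on EV in 10 of 15 cases and higher in 2 (median -1.33), with TNFRSF4 12.5-fold lower and PDCD1 6.61-fold lower. For P392L over EV the median was 0.56, at percentile 94.0 of random lists.

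Because CD28 and IL2RA were high on P392L, a hypothesis was that T cells there were more activated, beyond being more abundant. The activation median minus the T and NK cell marker median was -0.036 (bootstrap SE over genes 0.566), so activation and abundance cannot be told apart by these lists in this comparison. In the others the medians were -1.33 for activation and -0.07 for the markers in WT over EV, and 0.56 and 2.05 in P392L over EV. Whether the lists differ there was not tested.

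CDKN1A was 32.8-fold higher on P392L than on WT, and a hypothesis was that other p53 target genes would be higher with it. Their median log2 fold lay at percentile 100 of 10000 random lists (median 1.21), with 12 of 20 genes at least 2-fold higher and 2 lower. TIGAR was 4.14-fold higher, PLK3 3.86-fold higher and FAS 3.15-fold higher, while MDM2, a main target of p53, was 1.55-fold higher and GADD45A 1.02-fold lower. For P392L over EV the list lay within the middle 95% of random lists (median 0.34, percentile 90.5). For WT over EV it did too, on the low side (median -0.28, percentile 4.92), with 1 of 20 genes higher and 5 lower. The list's median for P392L over WT went the way the hypothesis needs, although 6 of its genes lay within 2-fold. A low level on WT may account for part of it, and the slide and the cell content stay open as other sources.

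APOE, APOC1 and C1QC were lower on P392L, and a hypothesis was that mature macrophages were fewer among the monocytic cells. The median of further macrophage genes minus that of further monocyte genes was -0.294 for P392L over WT (bootstrap SE over genes 0.663), with medians of -0.07 and 0.22, which leaves this open. Single genes went far both ways. Of 16 macrophage genes 6 were at least 2-fold lower and 1 higher. SELENOP was at least 52.1-fold lower and PLTP 9.66-fold lower, while MMD was 6.64-fold higher. Of 20 monocyte genes 7 were higher and 4 lower. THBS1, also a platelet gene, was 16.4-fold higher and CD52 4.86-fold higher, while MNDA was 5.71-fold lower.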
